A study of Pseudomonas fragi with 12 samples.

How the data were processed

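Total RNA from 12 samples of P. fragi 1793 biofilm on beef was sequenced, with 4 samples each at 48 h, 76 h and 115 h. RNA was extracted with a silica-column kit and made into Illumina libraries, per the labels' protocols. The reads were aligned with BWA and compared with limma, per the submitters' processing notes. The genome build, the annotation, the read counter, its strand setting and any removal of ribosomal RNA are not given in the sources used here. Reads shared by paralogs, overlapping genes or antisense genes therefore cannot be told apart, and values of such genes are uncertain.

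The deposited tables hold, per the file headers, raw read counts per locus tag for each library, with no normalization. The authors' log2 fold changes and mean log2 expression, and the authors' p-values with their adjusted form, stand in the same tables. A further deposited table gives log2 fold changes, p-values, reads summed over libraries and, as scores, the moderated t statistic and log odds of the authors' limma fit. The sum of reads of that table equals the sum over the 48 h and 115 h libraries for all of its 3193 genes. Another 23 columns of CPM values per sample were not used.

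The count columns carry no age and no replicate number in their names. Each table is titled by the stages it compares, so the columns shared by both tables of a stage belong to that stage, and initiation, maturation and dispersal were taken as 48 h, 76 h and 115 h in the order of their meaning. The labels' replicate numbers could not be tied to columns. Counts of a library were identical in each table that holds it. Of 4558 locus tags in the tables, 2 had no count in 1 library and were left out. The totals were 14011265 to 25030900 counted reads per library. No pair of libraries of 1 group agreed within sampling noise: the lowest chi-square per degree of freedom was 13.2, so no pair was merged as 1 library deposited again. This does not show that the libraries came from separate biofilms.

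Counts were tested in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood F test with robust dispersion, TMM scaling and the filterByExpr filter (minimum count 10), which left out 8 genes. All 12 libraries entered 1 fit with age as the factor, so the 3 comparisons share 1 estimate of spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are on TMM-scaled library sizes, and principal components and distances used log2 CPM with a prior count of 2. Shares of reads were compared by exact permutation of libraries.

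The design and the alternatives were fixed before the data were examined. The alternatives fixed in this way were upper-quartile scaling, DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, no low-count filter, a stricter filter (CPM of at least 10 in at least 4 libraries), a fit of only the 2 ages compared, a 2-fold and a 0.01 threshold, removal of the 10 genes with the most reads, and leaving out each library in turn. Limma-voom with library quality weights, and DESeq2 and limma-voom without 76 h library 1, were added after the data had been seen. The tests were checked on counts simulated from these libraries' means and sizes. Apart from the changed genes, each gene had the same mean at all ages, and counts were drawn independently. No simulated library stood apart as 76 h library 1 does, so the rates may not hold for the real libraries. For 76 h against 48 h, edgeR recovered 46% of genes changed by 1 and 92% of genes changed by 2 on the log2 scale (4547 genes). For 115 h against 76 h it recovered 66% and 95% (4548 genes), and for 115 h against 48 h 54% and 92% (4546 genes). In the simulation of 115 h against 76 h, edgeR called 3 and DESeq2 36 of the 4348 unchanged genes, and DESeq2 recovered 81% and 97% of the changed ones.

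The rule for named genes took, in each comparison, the called genes with the largest rise and fall whose groups did not overlap and that had a gene symbol. The tables do not pair locus tags with symbols or products, so the symbol condition was dropped and the rule was cut to the 2 largest rises and the 2 largest falls of 115 h against 48 h, which are named in every comparison. For the same reason the 40 gene lists written in advance and the tests of functional categories named in the study's design were not run.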

Results

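RNA was sequenced from biofilms of Pseudomonas fragi strain 1793, a Gram-negative bacterium that spoils chilled meat, grown on surface-sterilized beef kept at 10 °C in air. Biofilms were sampled at 3 ages, 48 h, 76 h and 115 h, with 4 libraries at each age. The study compares biofilm initiation, maturation and dispersal, and these stages were matched to the 3 ages in that order here, an assignment that the labels do not state. Reads were available as counts for 4556 locus tags, and 4548 of them passed the low-count filter and were tested. The libraries held between 14011265 and 25030900 counted reads, and the median locus tag had 884.5 to 1717 reads in a library. The tables name genes only by locus tag and do not pair the tags with gene names or functions, so no pathway can be named, and the results are given for the sets of genes that rose or fell and for 4 locus tags. Libraries are numbered within each age in the order of the numbers in the tables' column names, and these library numbers pair nothing between ages. The labels do not say whether the replicates came from separate cultures or beef cuts, so the p-values measure only the spread between these samples, which may be technical.

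Most of the variance between libraries lay along a single axis, on which the 48 h and 115 h libraries stood apart. The first principal component of log2 CPM (a gene's reads scaled to a fixed library total, with TMM-scaled library sizes) held 83.2% of the variance and the second 9.18%. On the line from the 48 h mean (0%) to the 115 h mean (100%), the 48 h libraries lay between -17.2% and 10.1% and the 115 h libraries between 88.8% and 102.6%. The 76 h libraries 2, 3 and 4 lay at 42.8%, 58.3% and 62.5%, and 76 h library 1 lay at 106.1%, beyond the highest 115 h library. Its mean distance to the 115 h libraries, as the root mean square of log2 differences over genes, was 0.539, against 1.20 to the other 76 h libraries. The counts of changed genes in the comparisons that use the 76 h group are therefore also given without this library, a choice made after its position had been seen.

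**Figure D1:**
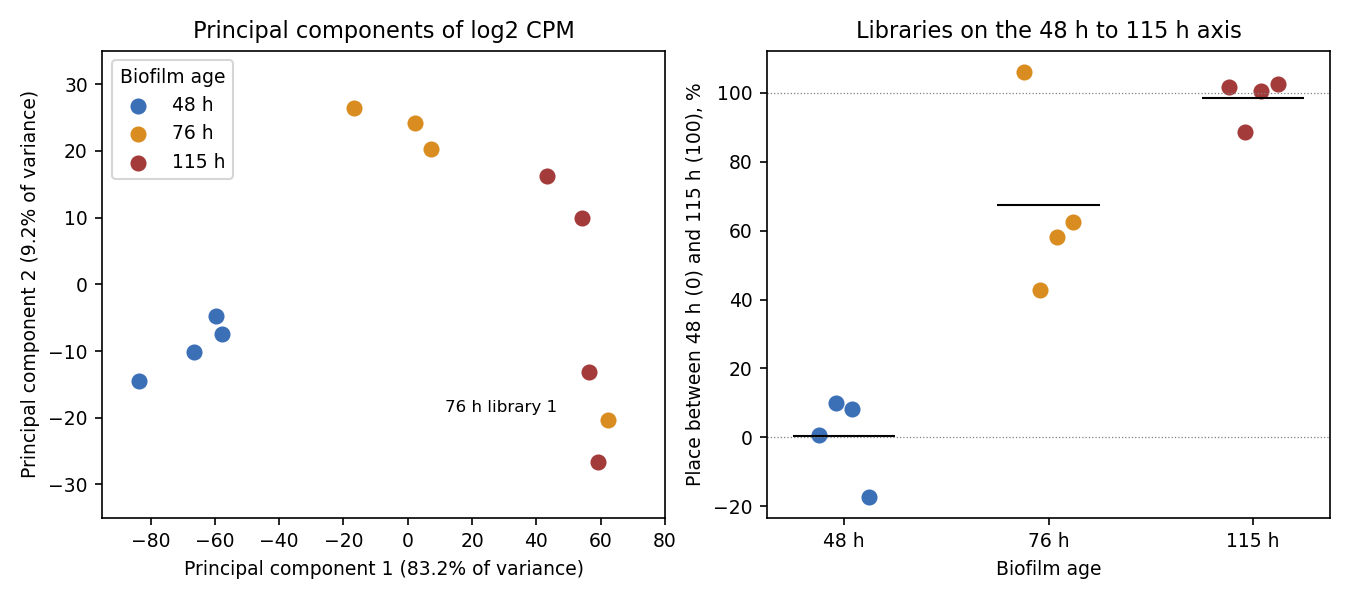
Left, the 12 libraries on the first 2 principal components of log2 CPM; right, the place of each library (point) on the line from the 48 h mean (0%) to the 115 h mean (100%), with the group mean as a bar; each library of 48 h and 115 h was placed on a line drawn without it. The 76 h libraries 2 to 4 lie between 42.8% and 62.5%, and 76 h library 1 lies at 106.1%.

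The first comparison asked which transcripts change from biofilm initiation to maturation, at 76 h against 48 h. Of the 4548 genes tested, 1531 rose and 1287 fell (62.0% of the genes; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Genes that rose did so by larger factors than genes that fell: 1034 rose and 442 fell at least 2-fold, and 221 rose and 5 fell at least 8-fold. CJU75_14375, which rose, went from 41.8 ± 18.2 CPM at 48 h to 3176 ± 4026 CPM at 76 h (SD, n = 4 each), a log2 fold change of 6.25 ± 0.91 (SE; edgeR adjusted p = 0.000208). CJU75_22455 also rose, from 74.4 ± 7.90 to 9369 ± 16918 CPM, with a log2 fold change of 6.98 ± 1.45 (edgeR adjusted p = 0.00185). The size of both changes rests on 76 h library 1, without which the log2 fold changes were 4.82 ± 0.51 for CJU75_14375 and 3.62 ± 0.53 for CJU75_22455 (edgeR adjusted p = 1.88e-05 and 0.000203). CJU75_09520 fell from 1188 ± 287 to 139 ± 82.2 CPM, a log2 fold change of -3.10 ± 0.44 (edgeR adjusted p = 0.000165). CJU75_12135 fell from 80.1 ± 8.36 to 19.9 ± 14.03 CPM, a log2 fold change of -2.01 ± 0.71 (edgeR adjusted p = 0.0272). Without 76 h library 1 the log2 fold changes were -2.79 ± 0.28 for CJU75_09520 and -1.62 ± 0.39 for CJU75_12135 (edgeR adjusted p = 1.25e-05 and 0.00453). The call for CJU75_12135 was lost without 48 h library 4 or without 76 h library 3 (edgeR adjusted p = 0.0553 and 0.0540).

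The values of the 2 ages did not overlap for 2692 genes, 59.2% of those tested, where chance gives 2.86%, and for 2966 genes (65.2%) without 76 h library 1, where chance gives 5.71%. The 5.71% does not allow for the choice of that library. With 76 h library 1 left out, 1425 genes rose and 1300 fell, and 2581 genes were called both with and without it, every one in the same direction. At least 8-fold rises numbered 97 without that library.

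The second comparison, 115 h against 76 h, addressed the step from maturation to dispersal. With all 8 libraries, edgeR called 0 genes, and its lowest adjusted p was 0.0848. At an unadjusted p under 0.05 it listed 1642 genes, the DESeq2 Wald test called 481 higher and 834 lower at 115 h, and limma-voom called 0. The values of the 2 ages did not overlap for 343 genes, 7.54% of those tested, against 2.86% by chance, and for 2678 genes (58.9%) without 76 h library 1, against 5.71% by chance. That library was left out because it lay with the 115 h libraries, which favours a difference between the 2 ages. The 5.71% and the p-values without it do not allow for this choice. Without 76 h library 1, edgeR called 1340 genes as higher and 1273 as lower at 115 h, of which 587 and 430 differed at least 2-fold, and 59 rose and 0 fell at least 8-fold. The DESeq2 Wald test and limma-voom then called 2742 and 2582 genes. No other single library had such an effect: leaving out 115 h library 4 gave 1 call, and leaving out any of the other 10 gave 0.

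The 4 named locus tags followed this count. In the test with all libraries CJU75_22455 stood 1.52 ± 1.14 and CJU75_14375 1.71 ± 0.74 higher at 115 h on the log2 scale, neither past the threshold (edgeR adjusted p = 0.327 and 0.124). The values for CJU75_09520 and CJU75_12135 were -1.49 ± 0.41 and -2.38 ± 0.74, also not past the threshold (edgeR adjusted p = 0.0848 for both). In the DESeq2 Wald test CJU75_14375, CJU75_09520 and CJU75_12135 passed (adjusted p = 0.0453, 0.00549 and 0.0167). Without 76 h library 1 all 4 passed in edgeR, with log2 fold changes of 4.88 ± 0.62 for CJU75_22455, 3.14 ± 0.51 for CJU75_14375, -1.80 ± 0.25 for CJU75_09520 and -2.78 ± 0.40 for CJU75_12135 (edgeR adjusted p = 0.000301, 0.000719, 0.000401 and 0.000448).

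**Figure D2:**
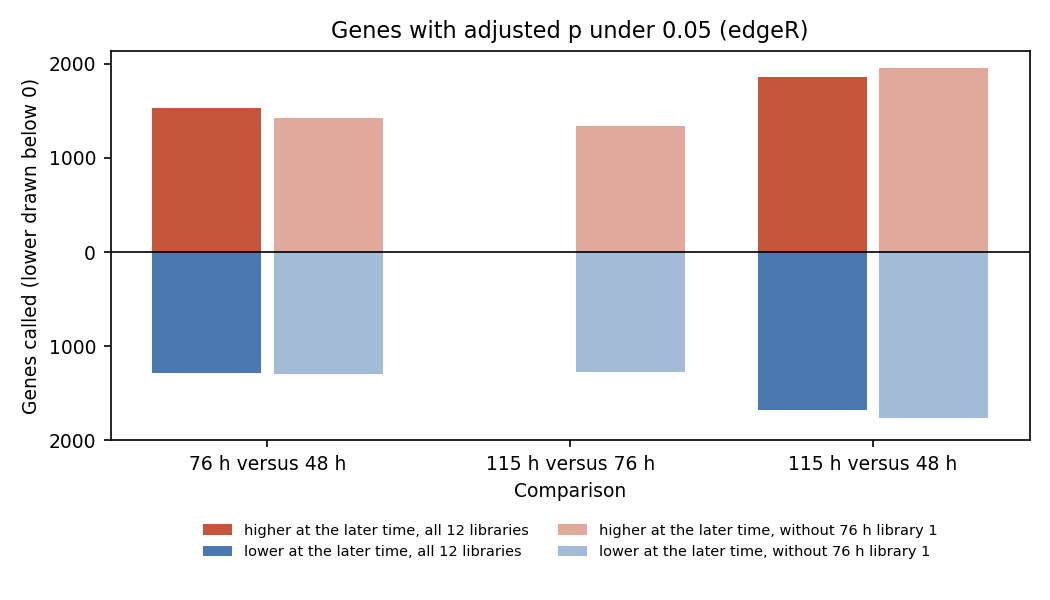
Number of genes called by edgeR (adjusted p under 0.05) in each comparison, higher at the later age above the line and lower below it, with all 12 libraries (dark) and without 76 h library 1 (light). For 115 h versus 76 h the count was 0 with all libraries and 2613 without that library.

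The third comparison set dispersal against initiation, 115 h against 48 h, and held the largest number of changes of the 3. At 115 h 1864 genes had risen and 1680 had fallen, together 77.9% of those tested (edgeR, adjusted p under 0.05). At least 2-fold changes comprised 1349 rises and 1004 falls, and at least 8-fold changes 357 rises and 56 falls. CJU75_22455 reached 26923 ± 18688 CPM at 115 h, 362-fold its 48 h level (log2 fold change 8.50 ± 1.54, edgeR adjusted p = 0.00037), and moved from rank 1859 by mean CPM at 48 h to rank 1. The mean rests on 115 h libraries 1 and 4, with 38430 and 47075 CPM. In 115 h libraries 2 and 3, with 9090 and 13097 CPM, another gene held the most reads. CJU75_14375 reached 10408 ± 2636 CPM, a log2 fold change of 7.96 ± 0.98 (edgeR adjusted p = 2.96e-05), and moved from rank 2498 to rank 8. CJU75_09520 fell to 49.2 ± 5.63 CPM, a log2 fold change of -4.59 ± 0.47 (edgeR adjusted p = 9.69e-06), and its rank went from 157 to 2558. CJU75_12135 fell to 3.80 ± 2.25 CPM, a log2 fold change of -4.39 ± 0.80 (edgeR adjusted p = 0.000366). The values of the 2 ages did not overlap for 3488 genes, 76.7% of those tested, where chance gives 2.86%. Leaving out 76 h library 1, which enters this comparison only through the shared filter, scaling and estimate of spread, kept all 3544 genes called in the same direction, among 3712.

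**Figure D3:**
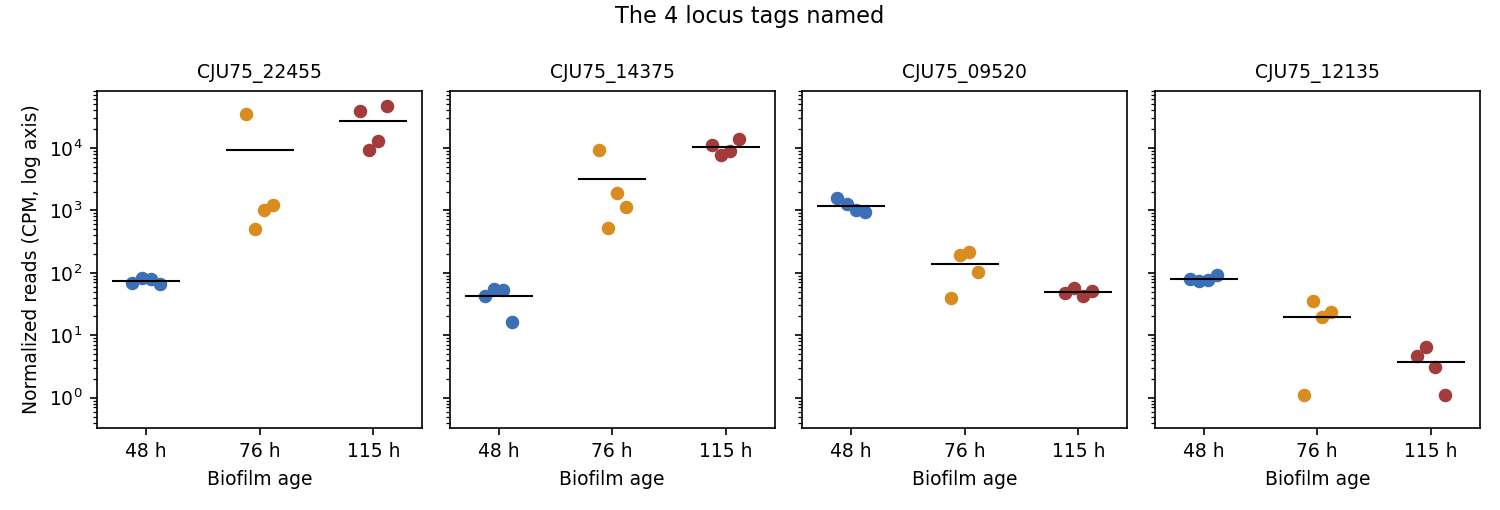
Normalized reads (CPM, log axis) of the 4 named locus tags in each library (points) at 48 h, 76 h and 115 h, with the mean of 4 libraries as a bar. At 76 h, library 1 (the leftmost point) held 34742 CPM of CJU75_22455, and the other 3 libraries held at most 1209 CPM.

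For the genes called between 48 h and 115 h, the 76 h mean was placed relative to the means of the 2 outer ages. These genes were chosen because the outer ages differ, which favours a 76 h mean between them, and no reference share was computed. Of the 1864 genes that rose, 1681 (90.2%) had a 76 h mean between those of the 2 other ages, and the median gene had gone 66.8% of the way on the log2 scale. Of the 1680 genes that fell, 1596 (95%) lay between, at a median of 63.8% of the way. In the 3 other 76 h libraries these medians were 54.7% and 51.04%, and 1622 of the rising and 1510 of the falling genes lay between. A test for a change at any age called 3420 genes (75.2%; edgeR, adjusted p under 0.05).

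The shift was also large in the share of reads. The 1864 genes that rose took 10.3 ± 2.20% of a library's reads at 48 h, 43.8 ± 16.03% at 76 h and 62.7 ± 3.16% at 115 h (SD, n = 4 each). The 1680 genes that fell took 78.9 ± 2.99%, 43.2 ± 14.5% and 25.8 ± 2.93%. The sets were chosen on the difference between 48 h and 115 h, so the contrast of those 2 ages follows in part from the choice. The rising genes took 66.9% of the reads in 76 h library 1 and 36.2 ± 5.60% in the 3 others (SD, n = 3). Of the 50 locus tags with the largest mean share of reads at an age, 48 h and 115 h shared 5, 48 h and 76 h shared 20, and 76 h and 115 h shared 31. With 76 h library 1 left out, 76 h shared more of these tags with 48 h (28) than with 115 h (23).

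**Figure D4:**
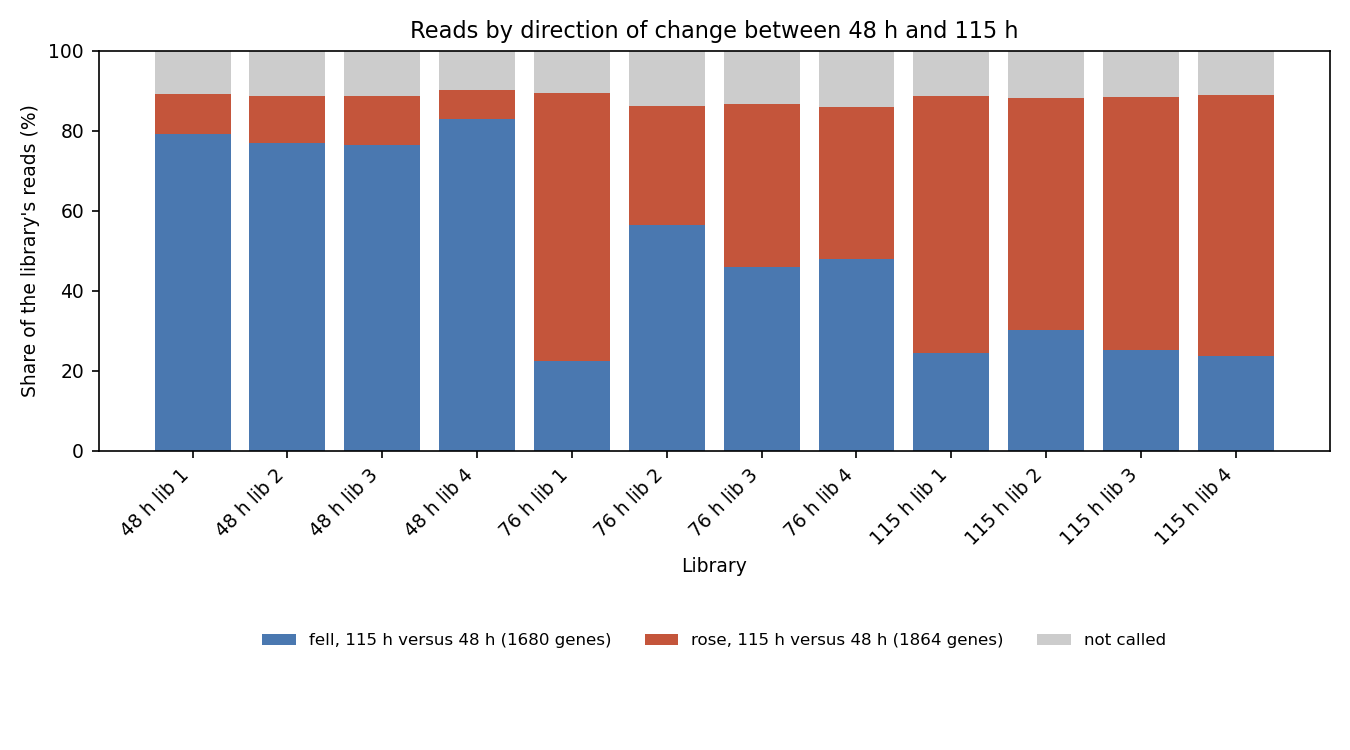
Share of each library's reads in the genes that fell (1680 genes) or rose (1864 genes) between 48 h and 115 h, or were not called; bars are single libraries. The rising genes hold 66.9% of the reads in 76 h library 1 and between 29.9% and 40.6% in the other 76 h libraries.

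The concentration of reads in a few genes differed less. The 10 most abundant genes took 10.96 ± 0.75% of reads at 48 h, 10.8 ± 4.06% at 76 h and 15.2 ± 2.09% at 115 h (SD, n = 4 each). At 76 h they took 16.6% in library 1 and 8.80 ± 1.27% in the 3 others (SD, n = 3). The difference between 115 h and 48 h had p = 0.0286 in a two-sided exact permutation test, the smallest that 4 against 4 libraries allow, and 0.0857 after Benjamini-Hochberg adjustment over 6 such tests, which does not pass. The number of genes that together held 50% of the reads was 156 ± 21.4 at 48 h, 216.5 ± 36.9 at 76 h (234 ± 14.2 without library 1, n = 3) and 196 ± 18.5 at 115 h (SD, n = 4 each). The difference between 115 h and 48 h had the same p-values in the exact permutation test. The 2 measures pointed opposite ways. At 115 h the 10 most abundant genes took more of the reads than at 48 h, but more genes were needed to hold 50% of them.

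The authors' deposited tables of the same comparisons gave similar counts for 2 of the 3. At an adjusted p under 0.05, the authors' deposited table of 76 h against 48 h called 1315 genes up and 1226 down, and the authors' deposited table of 115 h against 48 h called 1891 up and 1754 down. The authors' deposited table of 115 h against 76 h holds 7 libraries, without 115 h library 4, and called 21 genes up and 8 down. Of these 29 genes, 24 were tested here in the comparison with all 12 libraries, where 0 passed. Without 76 h library 1, 11 passed and 25 had the direction of the authors' table. Both counts cover only those of the 29 genes that were tested in that fit, a number that was not recorded. Of all genes tested without that library 57.4% passed, so the 11 alone are no sign of a match.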

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

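In 33 groups of 4 libraries, 3 held a library that stood apart from the rest of its group by its gap relative to the group's range. For independent, normally distributed values chance gives about 1 in 20 groups, or 1.65 of 33. The 33 groups hold several measures of the same libraries, and the 4 locus tags were picked for large changes. The 1.65 is therefore only a rough reference. All tests of explanations in this part were chosen after the result had been seen. CJU75_22455 stood at 34742 CPM in 76 h library 1, and the nearest other 76 h library held 1209 CPM. CJU75_14375 stood at 9156 CPM in the same library, against 1894 CPM in the nearest other. On the line from the 48 h mean to the 115 h mean, 115 h library 2 lay at 88.8%, and the nearest other 115 h library lay at 100.6%.

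Both gene values are part of a wider pattern: 76 h library 1 lies with the 115 h libraries, though the rule on gaps did not flag its place on the line. A swap with a 115 h library needs a partner among the 76 h libraries' values. The lowest 115 h library (library 2, at 88.8%) lay 26.3 percentage points above the highest of 76 h libraries 2 to 4. This is more than the 19.7 points those 3 span. The mean distance of 115 h library 2 was 0.568 to the other 115 h libraries and 0.798 to 76 h libraries 2 to 4. These values argue against a swap but do not exclude one. The same library lay closer to 76 h library 4 (0.635) than to 115 h library 4 (0.766). A 115 h library deposited again under a 76 h label would match its first copy within sampling noise, at a chi-square per degree of freedom near 1. The lowest value between 76 h library 1 and a 115 h library was 115 (library 4), which excludes such a match. That value is no larger than usual between 115 h libraries, whose pairs gave 91.3 to 561. The closest pair of libraries of 1 age, at 13.2, was of 48 h. A single 115 h library that carries a 76 h label stays open: the mean distance to the 115 h libraries, 0.539, is no larger than the largest distance between 2 of them, 0.766. A 76 h biofilm that had progressed further than the others may also account for the library's place at 106.1%. These 2 explanations cannot be told apart, because both put the library at the 115 h end and the labels give no other record of the sample.

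A second pattern is in the authors' deposited table of 115 h against 76 h, whose lowest adjusted p was 4.44e-183 while the median p of its 4557 genes was 0.741. A plain limma-voom fit of the 7 libraries in the table does not give these values: the log10 p-values of such a fit correlated with the deposited ones at 0.0465 across genes, and it called 0 genes, while the same fit matched both other tables at a correlation of 1. Genes with few reads are over-represented, since 18 of the 29 called genes averaged under 20 reads, as did 35 of all 4557 genes (two-sided Fisher's exact test, p = 1.39e-33). The deposited fold changes also follow a fit that gave 76 h library 1 almost no weight: its coefficient in a regression of the fold changes on the libraries' log2 CPM was -0.00274, where equal weights give -0.25. Fits with library quality weights or robust regression called 2418 and 1054 genes and correlated at 0.0142 and 0.0189 with the deposited log10 p-values, so the procedure behind the table stays open, and no biological explanation was tested.

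Other groupings of the libraries were refitted to ask whether chance alone gives as many calls. For 76 h against 48 h, 1 of the 35 splits of the 8 libraries, the real one, called as many as 2818 genes and the highest of the others called 0, which argues against chance. The same held for 115 h against 48 h, with 1 of 35 splits at 3544 genes and 0 in the highest other, and for a change at any age, with 1 of 100 groupings at 3420 genes and 0 in the highest other. In each case this is the smallest share that the groupings allow. The comparisons share libraries and were not adjusted for one another, so chance is not excluded. For 115 h against 76 h, all 35 of the 35 splits called at least the real 0, and the highest other called 2257. That split exchanges 76 h library 1 with 115 h library 2. The exchange with 115 h library 3 called 1572 genes, and the remaining splits called 0. Both splits put 76 h library 1 on the 115 h side, which points to a structure of the samples other than their labels, and neither shows that such an exchange took place. Without 76 h library 1, 1 of the 35 splits of the 7 libraries, the real one, reached 2613 calls, and the highest other called 1889. That library was left out because of its place, a choice the splits do not repeat, so these splits do not say whether chance gives as many calls. The split with 1889 calls moved 115 h library 2, the 115 h library nearest to 76 h, into the 76 h group.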

How the results depend on the processing

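Limma-voom with library quality weights, and DESeq2 and limma-voom without 76 h library 1, were chosen after the data had been seen. For 115 h against 76 h, where edgeR called 0 genes, the DESeq2 Wald test called 1315, and limma-voom with library quality weights called 2470. In simulated data DESeq2 called 36 of 4348 unchanged genes, where edgeR called 3. No simulated library stood apart as 76 h library 1 does, so these counts do not say how many of the 1315 calls are false. Leaving out single libraries gave 0 to 2613 calls for 115 h against 76 h, the highest without 76 h library 1 and 1 without 115 h library 4. Without 76 h library 1 DESeq2 called 2742 and limma-voom 2582. The cause was not tested beyond the place of that library. A 2-fold threshold lowered the counts to 1476 (1034 up, 442 down) for 76 h against 48 h and to 2353 for 115 h against 48 h, since fewer genes meet both conditions. Leaving out single libraries gave 2470 to 2929 calls for 76 h against 48 h, 3365 to 3712 for 115 h against 48 h and 3131 to 3794 for a change at any age. Genes called in both steps in opposite directions numbered 0, and 0 to 121 with single libraries left out, the highest again without 76 h library 1. All other planned settings kept the counts within 1.5 times. With DESeq2 size factors the calls split 1429 up to 1416 down for 76 h against 48 h and 1769 up to 1777 down for 115 h against 48 h. Without any normalization the median log2 fold change shifted by 0.15 and 0.12 in these comparisons, and all changes are relative to the TMM scaling. Of 180 values of the 4 named locus tags under the alternatives, 180 kept their direction and 171 their side of the threshold, 2 lost the call and 7 gained it. No paired analysis was possible because the count columns carry no replicate numbers. Removal of ribosomal and transfer RNA features and all gene list and category tests were not run, since the tables give no gene names. Depth limits little here: the median locus tag had at least 884.5 reads in every library.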

Other observations

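Genes with neighbouring locus tags moved in blocks. In 115 h against 48 h, 74 runs of at least 5 consecutive tags, with 591 genes, rose at least 2-fold throughout, and 42 such runs, with 327 genes, fell at least 2-fold throughout (edgeR, adjusted p under 0.05 for each gene). The falling runs took 40.1 ± 2.49% of reads at 48 h, 18.2 ± 7.78% at 76 h and 8.96 ± 1.83% at 115 h (SD, n = 4 each), and 21.9 ± 2.91% at 76 h without library 1 (n = 3). The rising runs went from 1.70 ± 0.45% at 48 h to 11.9 ± 6.82% at 76 h, or 8.52 ± 1.53% without library 1 (n = 3), and to 18.9 ± 0.97% at 115 h. The longest falling run held 40 consecutive tags, each with a log2 fold change between -3.29 and -1.64. This block took 21.4 ± 1.59% of all reads at 48 h, 8.43 ± 4.17% at 76 h (10.4 ± 1.55% without library 1, n = 3) and 3.51 ± 1.02% at 115 h. The longest rising runs were 2 runs of 18 tags. One had log2 fold changes between 1.13 and 7.63 and took 0.0572 ± 0.0175% of reads at 48 h and 1.25 ± 0.18% at 115 h. The other had log2 fold changes between 1.36 and 3.08 and took 0.0174 ± 0.0044% at 48 h and 0.0758 ± 0.0172% at 115 h. In 76 h against 48 h there were 51 rising and 10 falling runs (40 and 5 without 76 h library 1), and in 115 h against 76 h without 76 h library 1 there were 25 and 15.

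Whether a chance order of the tags gives such blocks was tested by shuffling the fold changes of 115 h against 48 h over the tags; this test was chosen after the result had been seen, and the removal of an abundance trend before. Fold changes of consecutive tags correlated at 0.596 across 4488 pairs of genes, and the highest of 1000 shuffles gave 0.0641, so the p was 0.001, the smallest that the shuffles can give; genes are not independent replicates. The highest number of genes in runs among the shuffles was 85 for rises and 38 for falls. A trend of the fold changes with abundance does not explain this, since the correlation was 0.537 after the trend had been removed. At a distance of 50 tags the correlation was 0.0204. The shuffles argue against a chance order and do not say why neighbours moved together. That genes numbered next to each other are transcribed together is a hypothesis, and it cannot be told apart from reads of 1 gene counted for its neighbour, since the tables give no strand, gene order or contig borders.

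The steps from 48 h to 76 h and from 76 h to 115 h called 0 genes in common with all 12 libraries. All 100 of 100 groupings of the libraries gave at least the real 0 of genes called in both steps in opposite directions, with 0 as the highest of the others, so this count says nothing. Without 76 h library 1, 1575 genes were called in both steps in the same direction and 121 in opposite directions, where independent lists of these sizes would share 784 and 782. Both steps use the 76 h libraries, with opposite signs, so chance deviations of these libraries push genes towards opposite directions and may add to the 121, not to the 1575. In 20 simulations of unchanged groups at most 0 genes of either kind were called, which gives no reference value for steps that both hold changes. With the 4 libraries of 76 h split 2 and 2 between the steps, the counts ranged from 0 to 1601 for the same direction and from 0 to 13 for opposite directions. They were above 0 only with 76 h library 1 in the first step, together with library 3 or 4.

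The authors' deposited table that covers 3193 genes of 115 h against 48 h listed 1067 genes up and 1572 down at an adjusted p under 0.05. Its median log2 fold change was -0.34 in the authors' deposited table and -0.23 for the same genes in the edgeR fit, which called 1131 of them up and 1442 down. The genes in that table are those with at least 4585 reads over the 8 libraries, and over all tested genes the median was 0.12.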
